A study of Mus musculus with 6 samples.

How the data were processed

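Total RNA was taken from the epididymal fat of 6 samples of male mice, 3 control (Tfrcfl/fl) and 3 knockout (TfrcAKO), extracted with Trizol and made into libraries with the NEBNext Ultra RNA kit, per the labels' protocols. Per the submitters' processing notes, CASAVA and FastQC were used, reads were handled with STAR 2.5 and HTSeq 0.6.1, and the build was mm10. The strand setting, the annotation release and any filters are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. The deposited table gives FPKM per gene, fragments per kilobase of gene length and 1000000 reads, per the file headers, with one column per sample. Its other numeric column, the gene length in bases, has no unit of expression and was used as deposited.

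The deposited FPKM times gene length in kilobases summed to 1000000 in each sample, so the authors' values are relative to the reads assigned to the genes of the table. Within each sample all values were whole multiples of one step within 0.01 of a read (100% of values above 0), which gave back the reads per gene and the depth of 25252839 to 30650624 gene-assigned reads. A count of 3 on a 2 kb gene corresponds to 0.0489 to 0.0594 FPKM, a limit that covers counting error only. Every pair of replicates differed by more than counting noise, with a chi-square per degree of freedom between 15.5 and 98.1 over 17046 to 17661 genes, so no library was counted as a repeat of another. The comparison cannot tell a separate animal from a repeat library of the same RNA, which can also exceed counting noise. The labels name mice but do not state that each sample is a separate animal, so p-values measure the spread between these samples.

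Gene identifiers are those of the table. Of 35275 identifiers, 34490 were found in the GENCODE M21 gene name table for GRCm38, and 99.88% of these overlapped their position there. Among the deposited names 27 had been turned into dates, and all 27 got their symbol back through the identifier. Of 805 list entries 803 were found in the table by symbol or older symbol.

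Genes with at least 0.5 FPKM in 3 or more samples were kept, which left 14383, and log2(FPKM + 0.5) was fitted with limma 3.58.1 (R 4.3.3, statmod 1.5.0) with 1 coefficient for the genotype, trend and robust empirical Bayes moderation, two-sided tests and Benjamini-Hochberg adjustment over all tested genes. A count model had been planned first for tables of counts; as the values are FPKM, the limma fit named in the same plan for such values was used. Of the alternatives for counts, limma-voom was run on the recovered reads and the others were not run. The 41 gene lists, 26 of pathways and 15 of cell types, were written before the data were examined. Those with at least 5 tested members (40) were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the 40 lists. Standard errors given beside log2 fold changes are those of limma.

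The genes named were set by a rule fixed in advance. It takes Tfrc; the 8 genes with the largest change in each direction among called genes with a mean of at least 5 FPKM and groups that do not overlap, leaving out predicted genes and immunoglobulin or T-cell receptor segments; for each list up to 4 called members with the smallest p, or the 2 most abundant members where none was called; and Fth1, Ftl1, Slc40a1, Slc11a2, Adipoq and Lep in any case. The rule gave 167 genes, from which examples are given; some of them are not reported here.

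Set before the data were seen were also pseudocounts of 0.1 and 1, a filter at 1 FPKM in 3 samples, no filter, the replicate number as a block, each sample left out in turn and limma-voom on the recovered reads. Chosen after seeing the data were median-of-ratios scaling, leaving out Yam1 with rescaling, leaving out knockout replicate 3 with control replicate 2, limma treat at 1.5-fold, and a composition score as covariate. The composition score of a sample is the mean log2 value of the mature adipocyte list minus that of the macrophage list.

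The procedure was tested on simulated data, with reads drawn from the control means and real depths in the same layout of 3 against 3 and 200 genes changed. Over 14193 genes tested there, the simulated comparison recovered 18.8% of genes changed 1.5-fold, 59.6% at 2-fold, 87.0% at 4-fold and 97.9% at 8-fold. It called 2 of 13987 unchanged genes. The real comparison called 6253 of 14383 genes, so the adjustment set a stricter cutoff in the simulation. These shares are therefore not the sensitivity of the real comparison. A simulated rise of 2-fold in the clock list gave a camera adjusted p of 1.16e-23 with the preset correlation and 0.0144 with the estimated one, and no other list was called in that simulation. Genes were drawn independently of each other there, so the simulation does not test lists whose members vary together. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.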

Results

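RNA sequencing measured mRNA abundance in epididymal adipose tissue, the visceral fat depot beside the testis, of male C57BL/6 mice. The 3 control samples came from mice labelled Tfrcfl/fl, in which both copies of Tfrc carry loxP sites. The 3 knockout samples came from mice labelled TfrcAKO, known as an adipocyte-specific deletion of the gene; the labels do not spell the abbreviation out. All mice started a diet with 60% fat at 2 months of age, stayed on it for 10 weeks and were sampled at 4.5 months. The deposited values are FPKM for 35275 genes, of which 10069 were listed at 0 in all 6 samples. The reads assigned to genes, recovered from the values, ranged from 25252839 in knockout replicate 3 to 30650624 in knockout replicate 1. At that depth 3 reads on a gene of 2 kb correspond to between 0.0489 and 0.0594 FPKM. The comparison asked which mRNAs of the fat depot differ when adipocytes lack Tfrc, the transferrin receptor that carries iron-loaded transferrin into cells.

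Tfrc itself (ENSMUSG00000022797, mm10 chromosome 16, 32608920 to 32632794, plus strand) was lower in every knockout sample than in any control sample. The control values were 11.1, 13.2 and 11.9 FPKM for replicates 1, 2 and 3, and the knockout values were 7.10, 8.27 and 9.50 FPKM. The means were 12.1 ± 1.08 (SD, n = 3) in control and 8.29 ± 1.20 (SD, n = 3) in knockout tissue. Tfrc fell by 0.52 on the log2(FPKM + 0.5) scale, with a standard error of 0.12 and a limma adjusted p of 0.0147. Leaving out control replicate 2 gave an adjusted p of 0.0595 and leaving out control replicate 3 gave 0.0525, both from limma. A value per gene also counts reads from exons outside a deleted part and from cells other than adipocytes, so it is no measure of how complete the deletion was.

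Of 14383 genes tested, 6253 differed between knockout and control tissue in limma at an adjusted p under 0.05, 3147 of them higher and 3106 lower in the knockout. Among these, 656 were higher by more than 1 and 761 lower by more than 1 on the log2 scale, and the median over all tested genes was −0.03. The count was 3336 without control replicate 2 and 3421 without control replicate 3. With the requirement that the change exceed 1.5-fold (limma treat), 56 genes were called, 39 higher and 17 lower. The first principal component held 78.3% of the variance and separated the groups, with control samples between −41.7 and −28.6 and knockout samples at 21.7, 25.2 and 60.9. Knockout replicate 3 was the sample at 60.9. Pearson correlations between samples, taken across genes, ranged from 0.989 to 0.992 within control, from 0.975 to 0.990 within knockout and from 0.907 to 0.967 between the groups. Without knockout replicate 3 limma called 5861 genes. Without both that library and control replicate 2, in which the lincRNA Yam1 was low, it called 4616.

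The 8 largest increases that met the naming rule were those of Cyp2e1, Pck1, Gsta4, Adrb3, Car3, Cfd, Thrsp and Retnla. Cyp2e1, a cytochrome P450 (ENSMUSG00000025479, chromosome 7, 140763739 to 140774975), was at 24.1, 14.3 and 21.7 FPKM in control replicates 1, 2 and 3 and at 231, 262 and 1096 FPKM in knockout replicates 1, 2 and 3, a log2 fold change of 4.33 ± 0.59 (SE). Its change was 3.62 without knockout replicate 3. Pck1, the phosphoenolpyruvate carboxykinase of glyceroneogenesis, rose by 3.34 ± 0.35, and Gsta4, a glutathione S-transferase that conjugates lipid aldehydes, by 3.30 ± 0.26. Adrb3, the β3-adrenergic receptor, rose by 3.27 ± 0.38. Car3, Cfd (adipsin) and Thrsp rose by 2.74 ± 0.39, 2.68 ± 0.36 and 2.59 ± 0.38. Retnla (ENSMUSG00000061100, chromosome 16, 48842552 to 48844461) rose from 54.0 ± 10.1 to 322 ± 29.2 FPKM (SD, n = 3 each). It encodes a secreted protein made by alternatively activated macrophages, but a whole-tissue value does not show which cells made it. The 8 largest decreases were those of Serpinb9b, Cd5l, Clec4d, Mmp12, Rnf128, Spp1, Akr1b8 and Vsig8. Serpinb9b (ENSMUSG00000021403, chromosome 13, 33027416 to 33041884), one of a family of closely related serpins whose shared reads make it uncertain, went from 36.4 ± 14.6 to 1.03 ± 0.687 FPKM (SD, n = 3 each), a log2 fold change of −4.62 ± 0.42 (SE). Cd5l, a macrophage-secreted protein (ENSMUSG00000015854, chromosome 3, 87357881 to 87371074), had a log2 fold change of −3.84 ± 0.24, and Clec4d, a myeloid C-type lectin, −3.58 ± 0.38. Mmp12, Rnf128, Spp1, Akr1b8 and Vsig8 changed by −2.95 ± 0.48, −2.82 ± 0.45, −2.79 ± 0.56, −2.63 ± 0.25 and −2.54 ± 0.50. Without knockout replicate 3 the values were −2.40 for Mmp12, −2.27 for Rnf128, −2.13 for Spp1 and −1.94 for Vsig8, and Spp1 had −3.32 without knockout replicate 1. The limma adjusted p of these 16 genes lay between 0.00243 (Retnla) and 0.0101 (Spp1). The naming rule itself required a call and groups that do not overlap, and 8644 of the 14383 tested genes had such groups.

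Among iron-handling genes, the ferritin subunits, heme oxygenase and ferroportin fell while Steap4 and Hfe rose. Ftl1, the ferritin light chain (ENSMUSG00000050708, chromosome 7, 45457944 to 45459884), went from 9650 ± 991 to 3600 ± 873 FPKM (SD, n = 3 each), a log2 fold change of −1.45 ± 0.23 (SE, limma adjusted p = 0.00555). Fth1, the heavy chain (ENSMUSG00000024661, chromosome 19, 9982703 to 9985092), went from 4370 ± 676 to 2420 ± 253 FPKM, a log2 fold change of −0.85 ± 0.18 (SE, limma adjusted p = 0.0108). Both ferritin genes have processed copies elsewhere in the genome, so their values carry that uncertainty. Hmox1, which releases iron from heme, fell by 2.10 ± 0.19 and Slc40a1, the iron exporter ferroportin, by 1.36 ± 0.16 (limma adjusted p = 0.00343 and 0.00372). Steap4, a metalloreductase, rose by 1.41 ± 0.16 and Hfe by 0.68 ± 0.08 (limma adjusted p = 0.00370 for each). Slc11a2, the divalent metal transporter DMT1, had a log2 fold change of −0.18 ± 0.10 and a limma adjusted p of 0.173. Of the 25 tested members of the iron list, 7 rose and 7 fell, and the same numbers were found adjusted over the list alone; without control replicate 2 or 3, 4 fell. With members moving both ways, the list had a median of −0.12, a camera adjusted p of 0.963 and an adjusted p of 0.983 with an estimated correlation. Of 26 genes of heme and iron-sulfur cluster synthesis, 13 rose and 2 fell (13 and 2 adjusted over the list alone). They included Iscu (0.71 ± 0.08), Bola3 (0.89 ± 0.11), Isca2 (0.58 ± 0.07) and Glrx5 (0.78 ± 0.11), all of cluster assembly. For that list camera gave an adjusted p of 0.00456, against an adjusted p of 0.437 with an estimated correlation. In the same tissue the median log2 fold change was −1.12 over the macrophage markers and 1.47 over the mature adipocyte markers.

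**Figure D1:**
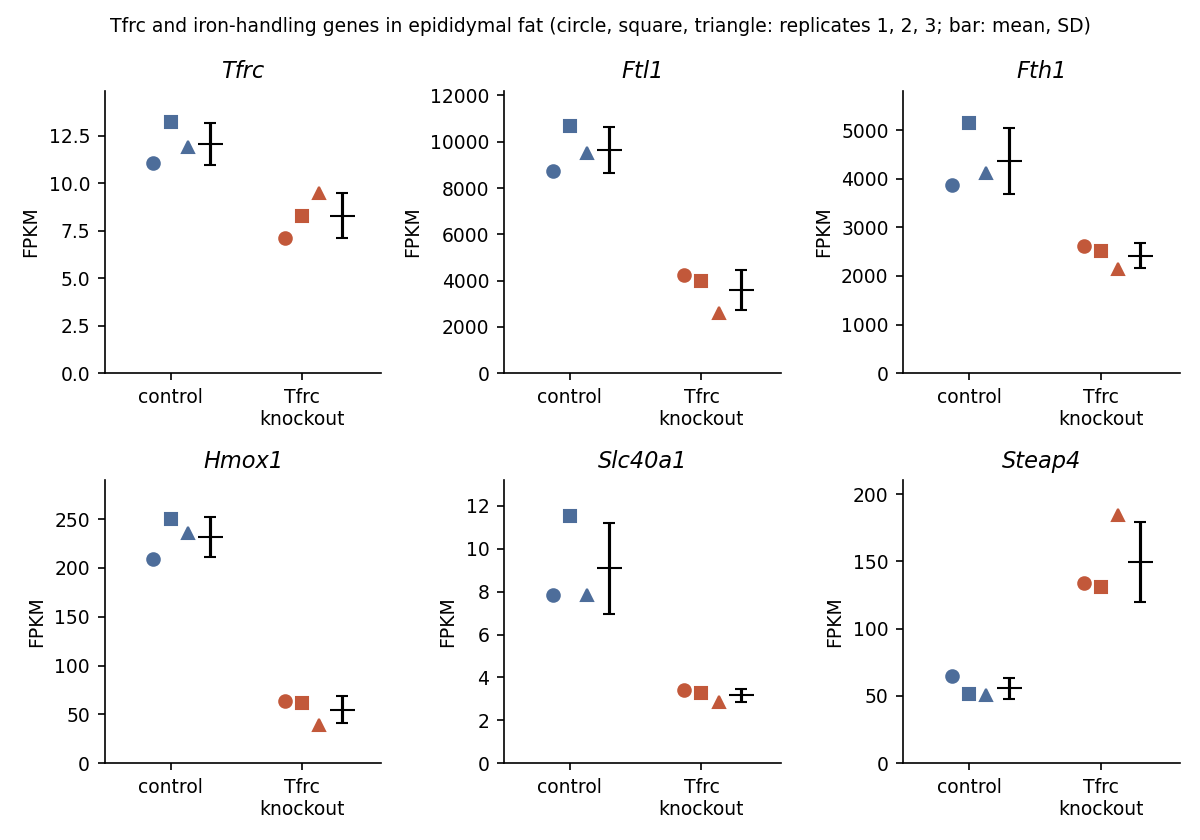
FPKM (linear y axes from 0) of Tfrc and 5 iron-handling genes in 3 control and 3 knockout samples, each point being a sample and each bar the mean with its SD. Ftl1 averaged 9650 FPKM in control and 3600 FPKM in knockout tissue, and for each of the 6 genes all knockout points lie on one side of the control points.

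Mature adipocyte markers and genes of lipid metabolism were higher in the knockout. Of 21 adipocyte markers 19 rose (20 adjusted over the list alone) and none fell. Without knockout replicate 3, 20 adipocyte markers rose and 1 fell. Adipoq, the adiponectin gene, rose from 384 ± 98.9 to 1460 ± 356 FPKM (SD, n = 3 each), a log2 fold change of 1.93 ± 0.24 (SE, limma adjusted p = 0.00373). Cidec, a lipid droplet protein, rose by 1.47 ± 0.18 (limma adjusted p = 0.00372). Lep, the leptin gene, had a log2 fold change of 0.48 ± 0.17 and a limma adjusted p of 0.062, which was 0.013 without knockout replicate 3. In triglyceride synthesis and lipolysis 17 of 20 genes rose and 1 fell (18 and 1 adjusted over the list alone), with Aqp7, the glycerol channel, at 1.57 ± 0.17 and Lpin1 at 1.47 ± 0.18. In de novo lipogenesis 13 of 18 rose and 1 fell (14 and 1 adjusted over the list alone). Pnpla3 and Elovl5 rose by 1.18 ± 0.14 and 0.54 ± 0.07, and Fads1, a fatty acid desaturase, fell by 0.73 ± 0.11. Without control replicate 2 or 3 the number higher in that list was 5 or 6. Its camera adjusted p was 0.000392 without control replicate 2 and 8.48e-05 without control replicate 3, or 0.5 and 0.471 with an estimated correlation. In insulin signalling and glucose uptake 12 of 17 rose and 2 fell (13 and 2 adjusted over the list alone), among them Pde3b (1.41 ± 0.23) upward and Akt1 (−0.53 ± 0.08) downward. Camera gave an adjusted p of 8.45e-08 for the adipocyte markers, 9.58e-07 for triglyceride genes, 0.000113 for lipogenesis and 0.00116 for insulin signalling. With an estimated correlation the adjusted p was 0.437 for each of the 4 lists. Of the 22 brown and beige adipocyte genes only 13 passed the filter, and 7 of these rose and 2 fell (7 and 2 adjusted over the list alone). The camera adjusted p was 0.0646, and the adjusted p was 0.437 with an estimated correlation. Adrb3, itself also a mature adipocyte marker here, Cox8b (1.74 ± 0.19), Cox7a1 (1.44 ± 0.14) and Kcnk3 (1.18 ± 0.19) were among those that rose. That list's camera adjusted p was under 0.05 in each of 5 fits that left out 1 library, the exception being knockout replicate 2, and between 0.0127 and 0.0359 in those 5; it was 0.0156 with a filter at 1 FPKM in 3 samples and 0.0277 with no filter. The number lower was 0 without any single control library.

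Many genes of mitochondrial fuel oxidation rose as well, in shares that differed between lists and, for several lists, dropped without control replicate 2 or 3. All 19 genes of the tricarboxylic acid cycle rose (19 adjusted over the list alone), including Suclg2 (0.90 ± 0.12), Idh3g (0.67 ± 0.11) and Idh3a (0.91 ± 0.15). Of 19 genes of branched-chain amino acid catabolism 18 rose and 1 fell (18 and 1 adjusted over the list alone). Bckdhb, a subunit of the branched-chain ketoacid dehydrogenase, rose by 1.85 ± 0.13 and Aldh6a1 by 1.62 ± 0.22. Of 22 fatty acid oxidation genes 19 rose and 1 fell (20 and 1 adjusted over the list alone), with Ehhadh at 1.68 ± 0.17 and Cpt2 at 0.90 ± 0.13. In respiratory complex I 28 of 35 genes rose and none fell (29 adjusted over the list alone), by a median of 0.36; Ndufv3 and Ndufs3 rose by 0.64 ± 0.09 and 0.65 ± 0.10. In complexes II and III 11 of 15 rose (14 adjusted over the list alone), among them Uqcr11 (0.61 ± 0.09). In complex IV 8 of 17 rose (8 adjusted over the list alone), among them Cox8a (0.65 ± 0.11). In ATP synthase 7 of 16 rose and 2 fell (8 and 3 adjusted over the list alone); Atp5k rose by 0.46 ± 0.07 and Atpif1, the inhibitor of the enzyme, fell by 1.11 ± 0.21. Of the 13 mRNAs encoded in mitochondrial DNA 6 rose (9 adjusted over the list alone), with mt-Nd2 at 0.76 ± 0.17 and a limma adjusted p of 0.0135, which was 0.0602 without control replicate 2 and 0.0623 without control replicate 3. Several of them overlap or have near-identical nuclear copies and are uncertain. Mitochondrial genes took 1.79% ± 0.08 of reads in control and 3.05% ± 0.91 in knockout tissue (SD, n = 3 each), and the highest share, 4.09%, was in knockout replicate 3. By camera the adjusted p was 4.21e-07 for the tricarboxylic acid cycle, 8.82e-08 for amino acid catabolism, 1.84e-07 for fatty acid oxidation, 5.42e-08 for complex I, 0.000113 for complexes II and III, 0.00529 for complex IV, 0.0156 for ATP synthase and 0.00328 for the mitochondrial mRNAs. With an estimated correlation the adjusted p was 0.504 for the mitochondrial mRNAs, 0.467 for complex IV and 0.437 for each of the other 6. Without control replicate 2 the numbers higher were 8 for the tricarboxylic acid cycle, 9 for complex I, 3 for complexes II and III, 1 for complex IV, 2 for ATP synthase and 0 for the mitochondrial mRNAs, and without control replicate 3 they were 9, 8, 3, 1, 2 and 0. Smaller losses came without control replicate 1, with 6 higher in complexes II and III, 3 in complex IV and 2 mitochondrial mRNAs, and without knockout replicate 2, with 18 higher in complex I and 4 in complex IV. Without knockout replicate 1, 12 mitochondrial mRNAs were higher. Without control replicate 2 the count over all tested genes fell too, from 6253 to 3336. In that fit mt-Nd2 and Sdha had log2 fold changes of 0.73 and 0.68, against 0.76 and 0.70 with all libraries. Its camera adjusted p was 2.42e-06 for the tricarboxylic acid cycle, 1.29e-07 for complex I and 0.00539 for the mitochondrial mRNAs. With an estimated correlation these were 0.5, 0.5 and 0.556. Fewer calls there thus need not mean smaller changes. The mature adipocyte markers, whose median was 1.47, moved in the same direction in the same samples.

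**Figure D2:**
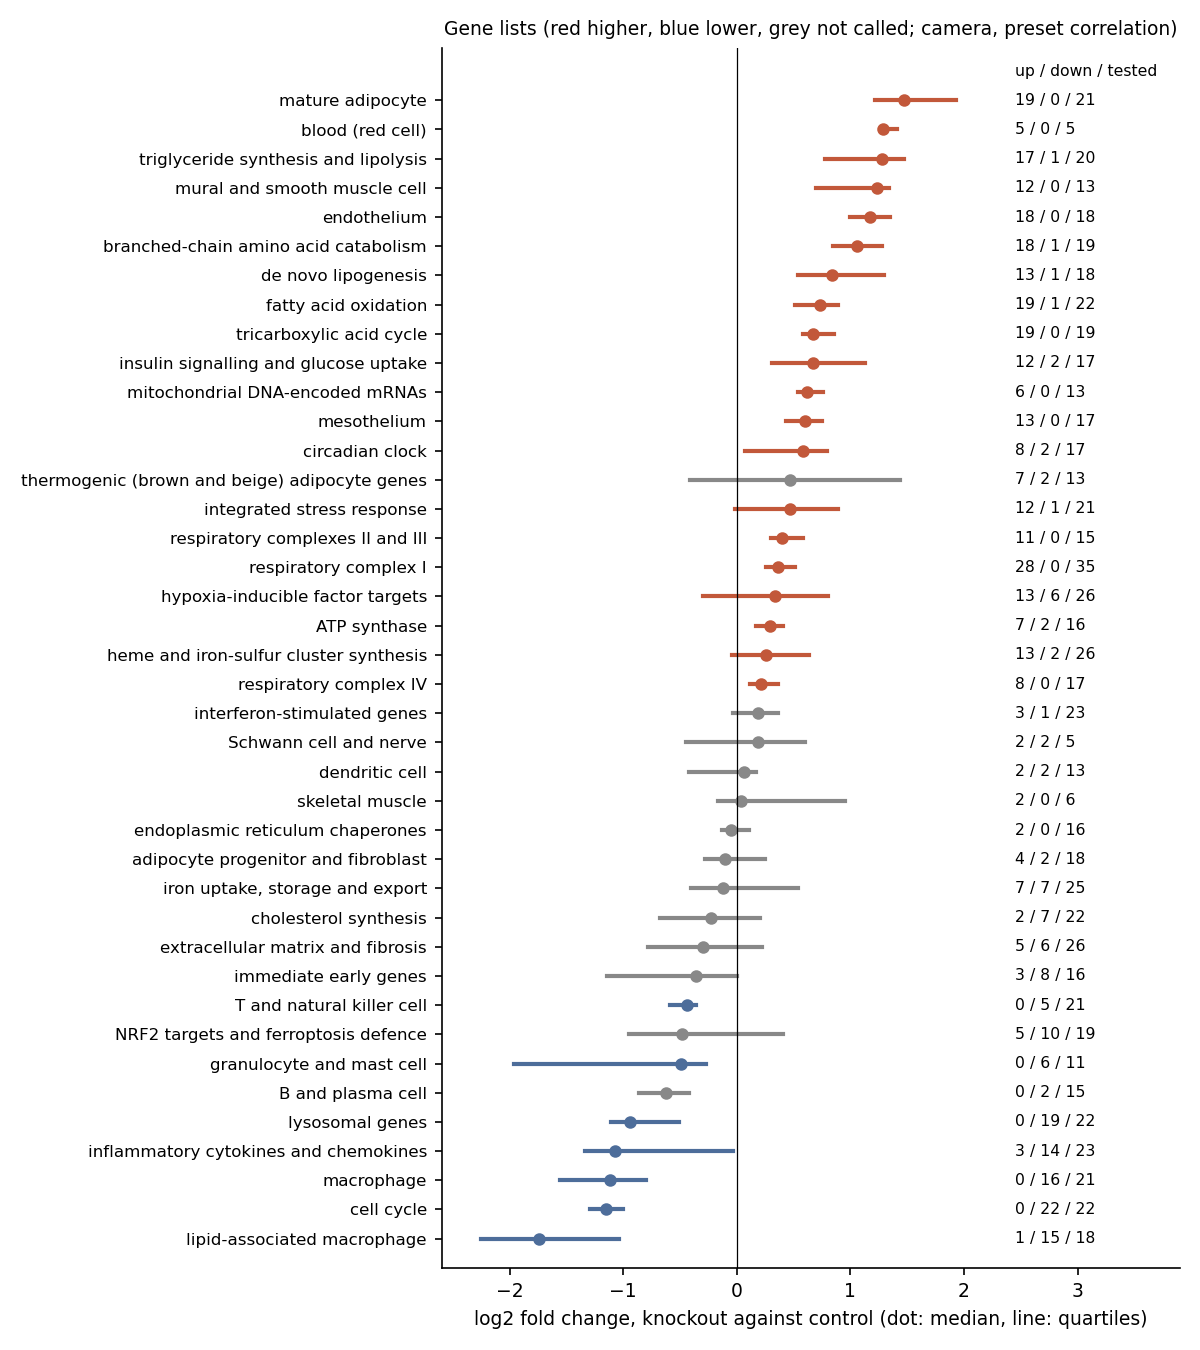
Median (dot) and quartiles (line) of the log2 fold change, knockout against control, over the tested members of 40 gene lists, with the numbers of members higher, lower and tested at the right. Mature adipocyte markers lie highest with a median of 1.47, and lipid-associated macrophage markers lie lowest with −1.74; colours give the camera call with a preset correlation, none of which was made with an estimated correlation.

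Most macrophage markers fell. Of 21 macrophage markers 16 fell and none rose (16 adjusted over the list alone), and without knockout replicate 3, 17 fell and 1 rose. The 3 with a fold change above 0, not called, were Lyve1 (0.45), Timd4 (0.34) and Cd163 (0.02). By fry the adjusted p of this list was 0.0563. Itgam, the CD11b integrin, went from 108 ± 14.4 to 32.8 ± 14.3 FPKM (SD, n = 3 each), a log2 fold change of −1.80 ± 0.34 (SE, limma adjusted p = 0.00827). Lyz2, lysozyme, went from 3280 ± 346 to 1180 ± 447 FPKM, and Mrc1 and Aif1 fell by 1.30 ± 0.26 and 0.95 ± 0.16. Of 18 markers of lipid-associated macrophages, the cells that gather around dying adipocytes in obese fat, 15 fell and 1 rose (16 and 1 adjusted over the list alone). Besides Clec4d and Mmp12, Dcstamp fell by 2.44 ± 0.39 and Syngr1 by 1.71 ± 0.30; the reads of Syngr1 may include some from the overlapping Rpl3. Of 22 lysosomal genes 19 fell and none rose (20 adjusted over the list alone), with Gla at −1.61 ± 0.25 and Npc1 at −0.98 ± 0.15. Without knockout replicate 3, 19 lysosomal genes fell and 1 rose. Of 23 cytokines and chemokines 14 fell and 3 rose (15 and 3 adjusted over the list alone). Ccl3 and Ccl4, chemoattractants of monocytes, fell by 2.23 ± 0.32 and 1.91 ± 0.15, and Tgfb1 by 1.09 ± 0.14, while Cxcl12 rose by 0.83 ± 0.09. All 22 cell cycle genes fell (22 adjusted over the list alone), among them Ccnb1 (−1.34 ± 0.19), Pcna (−1.29 ± 0.21) and Mcm3 (−1.03 ± 0.15). The adjusted p from camera was 0.000122 for macrophage markers, 1.57e-05 for lipid-associated macrophages, 4.84e-07 for lysosomal genes, 0.00726 for cytokines and 8.82e-08 for the cell cycle. With an estimated correlation the adjusted p was 0.487 for macrophage markers and cytokines and 0.437 for the other 3. The numbers lower without control replicate 2 were 6 macrophage markers, 9 lipid-associated macrophage markers and 9 cytokines. Without control replicate 3 they were 8 macrophage markers and 8 cytokines, and without control replicate 1 there were 9 cytokines. The camera adjusted p without control replicate 2 was 5.33e-05 for macrophage markers, 9.64e-06 for lipid-associated macrophages and 0.00479 for cytokines. With an estimated correlation these were 0.5, 0.5 and 0.51. The macrophage marker mean per sample was 6.72 ± 0.03 in control and 5.70 ± 0.56 in knockout tissue (log2 FPKM, SD, n = 3 each), with knockout replicate 3 lowest at 5.05.

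Markers of other leukocytes were lower or mixed. Of 11 tested granulocyte and mast cell genes 6 fell (7 adjusted over the list alone), and the 4 with the smallest p were the mast cell protease genes Cpa3 (−1.92 ± 0.28), Cma1 (−2.14 ± 0.40), Mcpt4 (−1.99 ± 0.40) and Tpsb2 (−2.14 ± 0.45). Camera gave this list an adjusted p of 0.0126, or 0.0575 without knockout replicate 3, and the adjusted p was 0.446 with an estimated correlation. Of 21 T and natural killer cell genes 5 fell (4 adjusted over the list alone), among them Gzmb (−0.95 ± 0.17) and Cd28 (−0.75 ± 0.15), both under 1 FPKM in the mean of either group. For these genes the camera adjusted p was 0.00328, the adjusted p was 0.437 with an estimated correlation, and with a filter at 1 FPKM in 3 samples the camera adjusted p was 0.144. The number of T and natural killer cell genes lower was 1 without control replicate 1 or 2, 2 without control replicate 3 and 9 without knockout replicate 1. Their camera adjusted p was 0.0423 without control replicate 1 and 0.00745 without control replicate 2, or 0.578 and 0.514 with an estimated correlation. Of 15 B and plasma cell genes 2 fell (0 adjusted over the list alone), Igkc and Cd22, with log2 fold changes of −1.15 ± 0.34 and −1.01 ± 0.33 a camera adjusted p of 0.0623 and an adjusted p of 0.668 with an estimated correlation. Neither gene was called without any 1 of the control libraries or without knockout replicate 2, and 5 B and plasma cell genes were lower without knockout replicate 1 and 3 without knockout replicate 3. Camera gave that list 0.00391 without control replicate 2, 0.00734 without knockout replicate 1 and 0.0193 with no filter. Of 13 dendritic cell genes 2 rose and 2 fell (2 and 2 adjusted over the list alone), with Zbtb46 at 0.78 ± 0.12 and Irf8 at −1.04 ± 0.20. The median of this list was 0.06 and its mean −0.06, with a camera adjusted p of 0.802, a direction of higher in that test and an adjusted p of 0.961 with an estimated correlation. Of 23 interferon-stimulated genes 3 rose and 1 fell (2 and 0 adjusted over the list alone), with Usp18 at 0.57 ± 0.10 and a camera adjusted p of 0.0854, or 0.548 with an estimated correlation. Without knockout replicate 2, 9 of them were higher and camera gave 0.0145, and without control replicate 3 camera gave 0.0447.

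Vascular markers rose in all knockout samples. Each of 18 endothelial genes rose (18 adjusted over the list alone) by a median of 1.17, among them Gpihbp1, which anchors lipoprotein lipase on capillaries (1.63 ± 0.17), Robo4 (1.52 ± 0.17) and Ptprb (1.23 ± 0.11). Of 13 mural and smooth muscle genes 12 rose (12 adjusted over the list alone), including Mylk (1.49 ± 0.12), Rgs5 (1.53 ± 0.16) and Acta2 (1.33 ± 0.12). Of 17 mesothelial genes 13 rose (13 adjusted over the list alone), including Msln (0.75 ± 0.07) and Upk3b (0.80 ± 0.11). All 5 tested red cell genes rose (5 adjusted over the list alone), with Hbb-bs going from 334 ± 94.8 to 781 ± 102 FPKM (SD, n = 3 each). Alas2, an erythroid gene of heme synthesis, rose by 1.12 ± 0.18. The globin genes are near-identical pairs, so the split between copies is uncertain. Camera gave an adjusted p of 7.48e-10 for endothelium, 3.40e-06 for mural cells and for mesothelium, and 0.00205 for red cells, and with an estimated correlation the adjusted p was 0.437 for each. Of 18 progenitor and fibroblast genes 4 rose and 2 fell (4 and 1 adjusted over the list alone), with Zfp423 at 0.68 ± 0.13 and Gsn at 0.86 ± 0.17, a list median of −0.10 and a camera adjusted p of 0.963 (0.983 with an estimated correlation); camera put the list lower and fry higher. Of 26 extracellular matrix genes 5 rose and 6 fell (5 and 9 adjusted over the list alone). Postn, periostin, fell by 1.15 ± 0.15, and Col4a2 and Sparc, of the basement membrane and matrix, rose by 0.62 ± 0.09 and 0.79 ± 0.14. For matrix genes the camera adjusted p was 0.521, or 0.940 with an estimated correlation. The number lower was 1 without any single control library and 12 without knockout replicate 1, and without knockout replicate 3 there were 9 higher and 11 lower. Of 6 skeletal muscle genes 2 rose (2 adjusted over the list alone), Acta1 (1.21 ± 0.15) and Myl1 (1.28 ± 0.18), with a camera adjusted p of 0.325, or 0.495 with an estimated correlation. Of 5 Schwann cell genes 2 rose and 2 fell (2 and 2 adjusted over the list alone), with Pmp22 at −0.59 ± 0.10 and a camera adjusted p of 0.963, or 0.983 with an estimated correlation. The epididymis and testis list had fewer than 5 tested members in the main fit and was not tested there. With no filter 18 of its members were tested, with a direction of higher and a camera adjusted p of 0.0599 (0.368 with an estimated correlation).

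**Figure D3:**
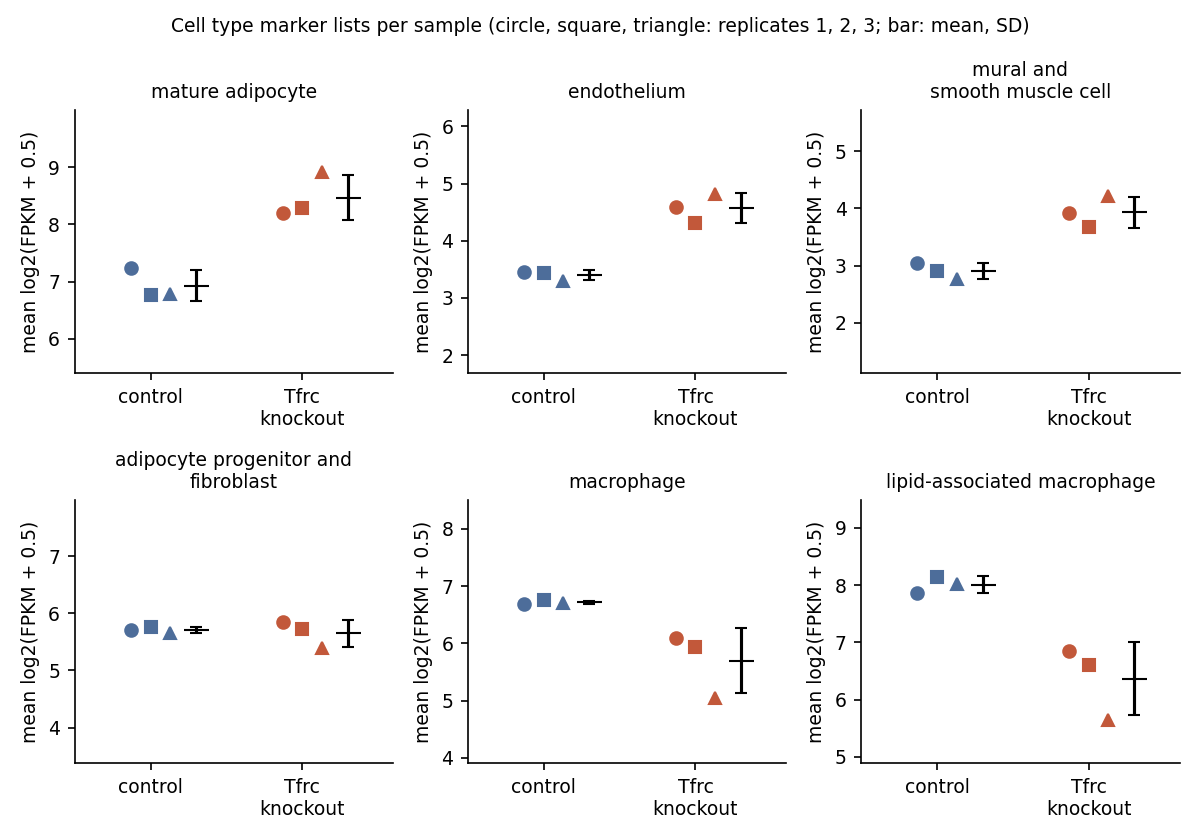
Mean log2(FPKM + 0.5) over 6 cell type marker lists in each of 3 control and 3 knockout samples, with the group mean and SD; each y axis spans the same range. Macrophage means are 6.69 to 6.75 in control and 5.05 to 6.10 in knockout samples, and progenitor means are 5.65 to 5.76 and 5.39 to 5.84.

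Stress-related lists moved in several directions. Of 21 genes of the integrated stress response 12 rose and 1 fell (12 and 1 adjusted over the list alone). Phgdh and Psat1, of serine synthesis, rose by 2.19 ± 0.23 and 0.97 ± 0.10, Sesn2 by 1.06 ± 0.10 and Nupr1 by 0.60 ± 0.07. Outside the naming rule, Gdf15 was the member that fell, with a log2 fold change of −1.77 (limma adjusted p = 0.00788). The other 8 were not called, among them Atf4 at −0.20 (limma adjusted p = 0.121) and Mthfd2 at −0.02 (0.855). Camera gave this list an adjusted p of 0.00258, and the adjusted p was 0.437 with an estimated correlation. Of 16 endoplasmic reticulum chaperone genes 2 rose (1 adjusted over the list alone), among them Herpud1 (0.51 ± 0.07), with a camera adjusted p of 0.963 (0.983 with an estimated correlation) and a list median of −0.05, of the opposite sign to the upward direction of the test. Without knockout replicate 3, 4 chaperone genes were higher and 1 lower, and without knockout replicate 1, 3 were lower. Of 26 targets of the hypoxia-inducible factors 13 rose and 6 fell (16 and 7 adjusted over the list alone). Vegfa, the angiogenic growth factor, rose by 2.21 ± 0.21, Bnip3 by 1.38 ± 0.17 and Adm by 1.04 ± 0.10. For that list the camera adjusted p was 0.0497, with an adjusted p of 0.437 with an estimated correlation. It was 0.0666 with median-of-ratios scaling, 0.0504 with a pseudocount of 1, 0.0533 without Yam1 and 0.0509 without knockout replicate 2. Of 19 NRF2 targets and ferroptosis defence genes 5 rose and 10 fell (7 and 10 adjusted over the list alone), with a camera adjusted p of 0.163 and an adjusted p of 0.437 with an estimated correlation; 3 rose without control replicate 3 and 7 without knockout replicate 3, by limma. Prdx1, a peroxiredoxin, went from 721 ± 168 to 167 ± 20.2 FPKM (SD, n = 3 each), a log2 fold change of −2.09 ± 0.19, and Srxn1 and Txnrd1, which regenerate peroxiredoxin and thioredoxin, fell by 1.86 ± 0.18 and 1.28 ± 0.12. Aifm2, a reductase that protects against lipid peroxidation, rose by 1.11 ± 0.13. The macrophage and adipocyte marker medians beside these lists were −1.12 and 1.47.

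Cholesterol, clock and immediate early genes moved in both directions. Of 22 cholesterol synthesis genes 2 rose and 7 fell (2 and 7 adjusted over the list alone), among them Sqle (−1.15 ± 0.15) and Srebf2 (−0.74 ± 0.12), with a camera adjusted p of 0.122, or 0.00346 without control replicate 2 and 0.0479 with no filter, and an adjusted p of 0.765 with an estimated correlation. Of 17 clock genes 8 rose and 2 fell (9 and 2 adjusted over the list alone). Nr1d1 and Cry2, repressors in the clock loop, rose by 1.65 ± 0.21 and 0.93 ± 0.18, and Npas2, an activator, fell by 1.15 ± 0.19. For clock genes the camera adjusted p was 0.0434, the adjusted p was 0.437 with an estimated correlation, and camera gave 0.0616 without control replicate 1 and 0.0682 without knockout replicate 3. The number of clock genes higher was 4 without control replicate 1 and 3 without control replicate 3. The hour of tissue collection was not given in the sources used here. Of 16 immediate early genes 3 rose and 8 fell (4 and 9 adjusted over the list alone), with Egr2 at −1.93 ± 0.35, Junb at −1.17 ± 0.16 and Btg2 at 0.46 ± 0.07. By camera the adjusted p was 0.106, 0.705 with an estimated correlation, 0.0471 without control replicate 1, 0.0299 without knockout replicate 1 and 0.0366 with no filter. The number lower was 2 without control replicate 2 or 3 and 4 without knockout replicate 2, and 1 gene was higher in every fit without 1 library except that without knockout replicate 3. The mature adipocyte and macrophage marker medians in the same tissue were 1.47 and −1.12.

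Over all lists, camera with the preset correlation called 27 of 40 lists at an adjusted p under 0.05, 20 of them higher and 7 lower in the knockout. With an estimated correlation camera called 0 of 40, the lowest adjusted p was 0.437, and 0 lists had an unadjusted p under 0.05, the lowest being 0.0747; fry, which asks whether the members move one way on balance, called 27, without the macrophage markers (adjusted p 0.0563) and the mitochondrial mRNAs (0.0643) and with the brown and beige adipocyte genes (0.0211) and the NRF2 targets (0.0135). Changes are on the log2(FPKM + 0.5) scale, which understates those of low genes, and 3 samples against 3 would allow an exact permutation p of 0.1 at the lowest for a single gene.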

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

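Median-of-ratios scaling, leaving out Yam1, leaving out knockout replicate 3 with control replicate 2, the 1.5-fold requirement and the composition covariate were chosen after the data had been seen. The Tfrc change stayed negative in each alternative run, between −0.62 and −0.42 when 1 library was left out. It lost its call without control replicate 2 (adjusted p 0.0595) and without control replicate 3 (0.0525); the adjusted p ranged from 0.00355 to 0.252 over all alternatives. With the composition score as covariate it was −0.89 with an adjusted p of 0.252, and −0.28 (95% interval −1.47 to 0.91) when knockout replicate 3 was also left out. The count of changed genes was 6253 and ran from 3336 to 5861 with 1 library left out; 3309 of the 3336 genes called without control replicate 2 were among the 6253, with the same direction. It was 56 with limma treat at 1.5-fold and 2 with the composition covariate, which uses 1 more coefficient and moves with genotype. The number of lists called, 27 of 40 tested, was between 26 and 30 with 1 library left out and 0 with an estimated correlation. The self-test did call a raised list that way, but its simulated genes varied independently of each other. In the real samples the estimated correlation was 0.80 for the endothelium list and 0.93 for the cell cycle list. The self-test therefore does not show whether a list could be called that way here. The estimated correlation was −0.02 for the hypoxia-inducible factor targets and 0.01 for the NRF2 targets. Their unadjusted camera p still rose, from 0.0335 to 0.0763 and from 0.134 to 0.214. For these lists a correlation above the preset 0.01 was not the reason. Pseudocounts, filters, limma-voom and both scalings gave 5347 to 6415 genes and 26 to 31 lists, and no scaling moved the median of all genes by more than 0.012. The replicate block gave 4581 genes, 28 lists and −0.52 for Tfrc; correlations of the deviations of same-numbered samples were −0.24, 0.03 and −0.18, and the deviations of 0 of 3 control samples correlated best with those of their own number. On the values themselves all 3 control samples had knockout replicate 1 as the closest of the knockout samples. That sample also lay nearest to the control group on the first principal component (21.7, against 25.2 and 60.9). Closeness therefore cannot tell whether the numbers pair the samples, and the correlations of deviations rest on 3 samples per group. With the block camera gave B and plasma cell genes 0.00579. For the 166 other named genes, 2394 of 2476 values kept direction and call, 80 lost the call, 2 gained it and 0 changed sign in the alternatives other than limma treat and the composition covariate. With that covariate 0 of the 167 named genes were called by limma and 19 changed sign. Other size factors, a Wald test, a fold threshold in a count model and a counts-per-million filter were planned for tables of counts and were not run on the recovered reads.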

Other observations

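The tests of scaling and cell types below, and the named genes Ass1 and Rbp7, were chosen after the results had been seen; the tests with the composition score were written before their outcome. With that score as covariate, limma called 2 genes for genotype, Ass1 and Rbp7, and 1758 at an unadjusted p under 0.05. Ass1, argininosuccinate synthase of arginine synthesis, rose by 2.15 without the covariate and had an adjusted effect of 2.49 (95% interval 2.02 to 2.97). Rbp7, a retinol-binding protein of capillary endothelium and adipocytes, rose by 2.26 and had an adjusted effect of 2.10 (1.78 to 2.42). The score holds only adipocyte and macrophage markers. It does not adjust for endothelial cells, whose markers rose by a median of 1.17. Without knockout replicate 3 the adjusted effects were 2.54 (1.40 to 3.67) and 2.04 (1.30 to 2.79). Retnla had 2.61 (1.74 to 3.47) with all libraries and 2.22 (−0.80 to 5.24) without knockout replicate 3. Yam1, a lincRNA on chromosome 17, was at 863 FPKM in control replicate 2 and between 8384 and 23731 FPKM in the other 5 samples.

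Macrophage markers were lower and mature adipocyte markers higher in the knockout. Scaling acts on all genes of a sample by the same factor, whereas the adipocyte list (median 1.47, quartiles 1.22 to 1.93) lay above the macrophage list (median −1.12, quartiles −1.56 to −0.80), a difference of 2.59, so scaling cannot account for both. A loss of macrophages alone would raise all other types alike, whereas the endothelial list (median 1.17, quartiles 1.00 to 1.35) lay above the progenitor list (median −0.10, quartiles −0.28 to 0.25), a difference of 1.27. Whether all macrophages fell alike stays open: 3 of the 19 macrophage markers with a mean of at least 5 FPKM, Cd163, Lyve1 and Mertk, had intervals above the list median of −1.12, but Lyve1 is also made by lymphatic endothelium and 3 genes are few.

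Ftl1, Fth1 and Hmox1, which macrophages express strongly, fell with the macrophage markers, and the composition score did not overlap between the groups (0.01 to 0.55 in control, 2.09 to 3.86 in knockout samples). With it as covariate the Ftl1 effect was −0.42 (95% interval −0.80 to −0.04), which by the bound set beforehand would argue against fewer macrophages as the whole cause. Without knockout replicate 3 the estimate was close, at −0.38, but the wider interval of that smaller fit included 0 (−1.13 to 0.38). The bound was thus met with all libraries and not in the smaller fit. Score and genotype also move together, so the question stays open. Fth1 had −0.35 (−0.90 to 0.21), and 0.22 (−0.90 to 1.34) without that library, where the sign reversed. Hmox1 had −1.06 (−1.34 to −0.78), and −1.06 (−1.69 to −0.43) without that library. Clec4d and Mmp12 of lipid-associated macrophages had −1.53 (−2.24 to −0.81) and −0.26 (−0.76 to 0.23) with all libraries and −0.20 (−1.09 to 0.69) and 0.58 (−0.15 to 1.31) without it. Most macrophage markers had estimates below 0 without it, and some had estimates above 0. Aif1 had −1.50 (−2.48 to −0.52) and Mrc1 −0.78 (−1.53 to −0.03), while Lyz2 had −0.27 (−0.98 to 0.43). Mertk, at 0.89 (0.01 to 1.77), was alone among them in having an interval above 0. Hmox1 thus kept its lower estimate in a fit that left most macrophage markers lower too. With all libraries Aif1 and Mrc1 had −0.31 (−0.99 to 0.36) and 0.07 (−0.43 to 0.57). As score and genotype move together, a lower Hmox1 level within cells and fewer cells that express it are not told apart.

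Integrated stress response genes called higher had a median of 0.83, and 0.62 with the composition score as covariate; 7 of the 12 kept an interval above 0 and 0 were called by limma. Without knockout replicate 3 the adjusted median was 0.17. More adipocytes relative to macrophages and a stress response in the adipocytes therefore cannot be told apart for these genes, because the score and the genotype move together.

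The 6 samples can be split into 3 and 3 in 10 ways, too few to bring the share of as large a result under 0.05. The real split called 6253 genes in limma, the highest of the other splits called 0 (at most 328 at an unadjusted p under 0.05), and 1 of the 10, the real one, reached 6253. For gene lists the real split called 27 with camera at the preset correlation, the highest of the others called 29, and 4 of the 10 reached 27.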
